A study of Mus musculus with 8 samples.

How the data were processed

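RNA was measured in sorted epithelial cells of the buccal (cheek) mucosa of wild type C57BL/6 mice kept under specific pathogen free conditions, 4 animals at 1 week and 4 at 8 weeks of age. Per the labels, the epithelium was separated from the mucosa with dispase II, epithelial cells were sorted by flow cytometry, and RNA was extracted from the frozen cells. Libraries were stranded total RNA libraries for low input, with depletion of ribosomal RNA. The labels give neither the gate of the sort nor the sex of the animals, and no batch.

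The deposited table held 1 column of raw read counts per library for 23355 Ensembl genes, each with at least 10 counts summed over the 8 libraries. It also held the authors' normalized signal, which equalled the counts divided by 1 size factor per library (0.838 to 1.36) to within a relative deviation of 1.42e-14. The authors' mean signal over the libraries, log2 fold change with its standard error, Wald score (the Wald statistic) and p-value with its adjusted p-value stood in the same table. The submitters' processing notes name bcl2fastq 2.20.0.422, cutadapt 2.10, TopHat2 2.1.1, HTSeq 0.6.0, DESeq2 1.26.0 and the GRCm38 build. Neither the release of the gene annotation nor the strand setting of HTSeq was given in the sources used here, so reads of an overlapping or antisense transcript can be part of a gene's count. Columns were matched to samples through the library names in the labels, and 0 columns of per-sample values were left unmatched. Gene positions are those of the deposited table. Transcript lengths, GC content and overlaps with small RNAs came from the GENCODE M21 annotation of GRCm38. It held 23320 of the genes (99.9%) by identifier, 99.2% of them with identical start and end.

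The counts, not the normalized signal, were tested in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, libraries were scaled by TMM, and 8 weeks was compared with 1 week by the quasi-likelihood F test, which is two-sided. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Log2 fold changes are 8 weeks over 1 week, their standard error (SE) was derived from the F statistic, and CPM values are those of the cpm function of edgeR with TMM-scaled libraries. The numbers printed as errors of CPM are standard deviations over the 4 libraries of a group.

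A total of 33 gene lists with 804 genes, for epithelial functions, signalling, metabolism, RNA quality and markers of other cell types, were fixed before the data were examined. Lists with at least 5 tested members (28 lists) were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. These lists were also tested with an estimated correlation and with fry. All 33 were tested by an exact two-sided permutation test on the mean log2(CPM + 1) of their tested members per library. For this test 0.0286 is the smallest p that 4 against 4 libraries can give. For each list the called members are counted over all genes tested and, separately, adjusted over the list alone. Across the lists 15 genes belonged to more than 1 list.

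The genes named were chosen by a rule also fixed before the data were examined. It took the 10 largest and 10 smallest log2 fold changes among called genes with a mean of at least 5 CPM, without overlap between the groups and without a predicted or clone-based symbol. It added the 3 members with the smallest p of each list, every called member of a list with fewer than 6 of them, the 5 most abundant genes of each group, 20 genes set in advance and a set of sex-linked genes. The rule gave 135 genes, of which the text names a part. A result that the rule includes is withheld and not reported here. Genes outside it are said to be chosen after their values were seen.

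The fit was tested on simulated counts with 200 changed genes. It recovered 25.4% of genes changed 1.5-fold, 64.2% of those changed 2-fold and 90.9% of those changed 4-fold, with 10 false calls (7.7% of the calls). With a simulated trend of the libraries on transcript length, the same fit made 286 false calls (69.2% of the calls). With a spline of each library on transcript length and on GC content (4 degrees of freedom each) as an offset, it made 7 (5.5%). The simulated trend was equal in all libraries of an age, opposite between the ages and without a GC trend. It was linear in the log of the same transcript length that the correction uses, so the correction was bound to remove it. The slopes of the real libraries varied within an age. This correction was added after the data had been seen, and its adjusted p is given where it ended the call of a gene named.

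Alternatives planned before the data were examined were the size factors of DESeq2, upper-quartile scaling, library size alone, no filter, a stricter filter (at least 5 CPM in 4 libraries), the Wald test of DESeq2 1.42.0, limma-voom with sample quality weights, a 2-fold minimum, each of 2 replicate blocks, each library left out in turn, and for the lists an estimated correlation, fry and lists without shared members. Sex as a covariate was not run, because Xist had 7565 to 45513 counts and Kdm5d at most 28 in every library, so that 1 sex alone was present. Added after the data had been seen were the length and GC correction, its own series with each library left out, protein-coding genes alone, and fits without 2 and without 3 libraries. The replicate numbers of the titles gave no sign of a pairing: the correlations between libraries with the same number, after removal of the group means, were -0.322, -0.147, -0.119 and -0.134. Trends on transcript length, with slopes of -0.174 in 1 week 1 and 0.199 in 8 weeks 1, could hide a shared factor. A pairing is therefore not excluded. The block of the library names was fitted on the 6 libraries whose number occurs at both ages, without 1 week 3 and 8 weeks 3. A change with that block can come from blocking or from the libraries left out.

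Total counts per library ran from 11747783 to 16807773. Before TMM scaling 1 CPM stands for 11.75 to 16.81 counts, and the counts limit the precision of genes near or under that level. Reads carried no molecular identifiers, so counting error is a lower limit of the technical error.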

Results

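Total RNA of sorted buccal epithelial cells was sequenced from 4 mice of 1 week and 4 mice of 8 weeks of age. The 4 libraries of 1 week (1 week 1 to 1 week 4) held 12764356, 13169992, 12114665 and 11747783 counts, and those of 8 weeks (8 weeks 1 to 8 weeks 4) held 16807773, 13037171, 15445210 and 14093048. Keratins of stratified epithelium were among the most abundant transcripts. Krt5, a keratin of basal cells, stood at 11114 ± 1063 CPM (SD, n = 4) at 1 week and 8454 ± 1883 CPM (SD, n = 4) at 8 weeks, and Krt13, a keratin of the upper layers of internal epithelia, at 7710 ± 810 and 8234 ± 852 CPM. The desmosomal gene Dsp stood at 6119 ± 239 and 7375 ± 125 CPM. By edgeR none of these 3 genes passed the test between the ages (adjusted p = 0.171, 0.709 and 0.195), while in the authors' DESeq2 table Dsp did (adjusted p = 0.00554).

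The series has 1 comparison, which asks how the transcripts of the oral epithelium differ between young and adult mice. At 8 weeks the keratins Krt17, Krt16 and Krt6b, known from hair follicles and from wounded or activated epithelium, were lower, and so were the microfibril gene Fbn2 and the chemokine gene Cxcl14. The cornified envelope gene Ppl, the tight junction genes Cgn and Magi1, the ceramide synthase gene Cers4 and the haemoglobin genes Hbb-bs, Hba-a1 and Hba-a2 were higher. Of 14533 genes tested, 484 were called higher and 468 lower at 8 weeks, 6.55% of the genes together. The median absolute log2 fold change of the called genes was 0.62, and 250 changed at least 2-fold (77 higher, 173 lower). The groups did not overlap in 834 of the 952 called genes. Over all tested genes this held for 14.8%, against 2.86% by chance.

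The called genes were not evenly spread over transcript length. With the tested protein-coding genes in 5 classes of transcript length, the median log2 fold change in the longest class was 0.21, with 301 genes called higher and 34 lower. In the shortest it was -0.25, with 16 higher and 170 lower. Slopes of expression on transcript length were fitted over 10366 protein-coding genes with a mean log2 CPM above 2. In log2 per doubling the slope was -0.17, -0.05, -0.07 and -0.07 in the 1 week libraries and 0.20, -0.02, 0.15 and 0.03 in the 8 weeks libraries. The difference between the ages was 0.18 (exact two-sided permutation test, p = 0.0286, the smallest that 4 against 4 libraries can give). After correction for transcript length and GC content 155 genes were called higher and 230 lower. Of the 952 uncorrected calls 336 were called again, with 0 in the opposite direction, 616 were not, and 49 further genes were called.

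**Figure D1:**
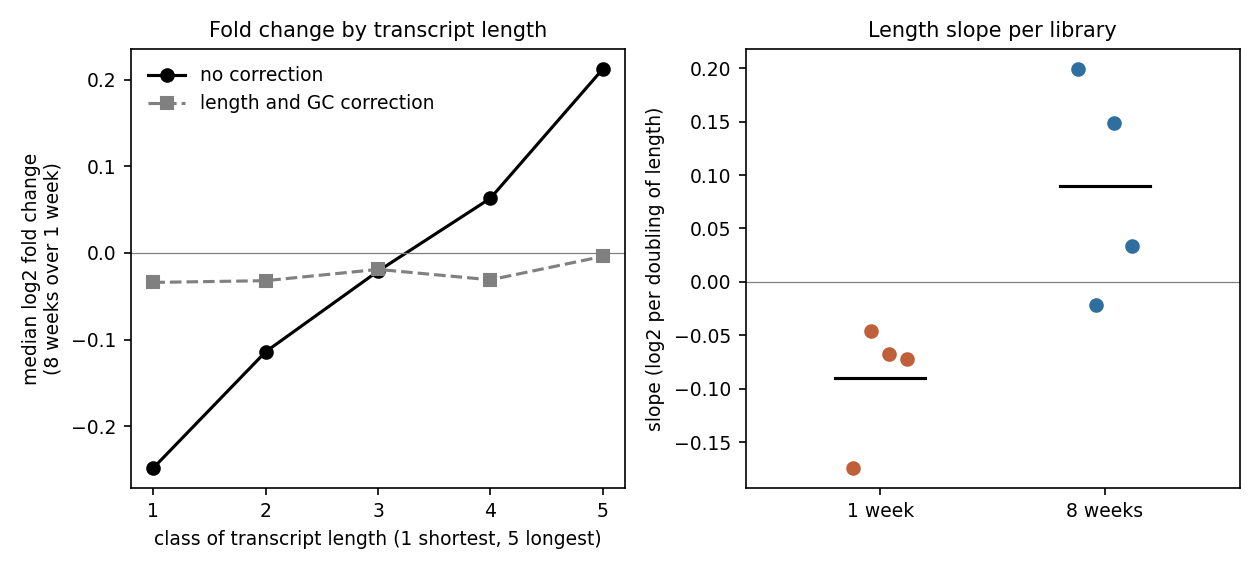
Left, median log2 fold change (8 weeks over 1 week) of tested protein-coding genes in each of 5 classes of transcript length, without correction (circles) and with length and GC correction (squares). Right, slope of expression on transcript length in log2 per doubling for each library over 10366 protein-coding genes, points by age and bars at the group mean. Without correction the medians run from -0.25 in the shortest class to 0.21 in the longest, and the 4 slopes of 1 week lie below the 4 of 8 weeks.

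Among genes of at least 5 CPM, Fbn2 (fibrillin 2, a microfibril protein of developing tissue; ENSMUSG00000024598, chromosome 18, 58008623 to 58210487) was 19.6 ± 1.92 CPM (SD, n = 4) at 1 week and 4.37 ± 1.27 CPM at 8 weeks. Its log2 fold change was -2.16 (SE 0.20, adjusted p = 0.00043). Plekha6, which encodes a protein with a pleckstrin homology domain (ENSMUSG00000041757, chromosome 1, 133164210 to 133303435), was 27.2 ± 4.64 CPM at 1 week and 75.4 ± 13.2 CPM at 8 weeks, a log2 fold change of 1.47 (SE 0.15, adjusted p = 0.00043). Higher by 4.89-fold was Gpr179, an orphan receptor gene, by 3.28-fold Ulbp1, a gene of a ligand of the NKG2D receptor, and by 3.23-fold the sulfotransferase gene Sult5a1. Sncaip, which encodes synphilin 1, was 4.03-fold lower. These 6 genes stayed under the threshold with each library left out in turn and with the length correction.

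The widest changes were those of Chil4, a chitinase-like gene, and Alox15, a lipoxygenase gene, which fell by 4.70 (SE 0.95, adjusted p = 0.0202) and by 4.34 (SE 0.82, adjusted p = 0.0165) on the log2 scale. Both varied widely among the 1 week libraries: Chil4 stood at 104 ± 150 CPM (SD, n = 4) and Alox15 at 18.9 ± 21.2 CPM, against 4.11 ± 3.79 and 0.90 ± 0.61 CPM at 8 weeks. Both were highest in 1 week 2 (328 and 49.0 CPM), without which the log2 fold changes were -2.86 and -3.25. Chil4 lost its call without 8 weeks 1 or 8 weeks 3 (highest adjusted p = 0.0668), Alox15 without 8 weeks 1 (0.0527), and both with limma-voom (0.0553 and 0.0997). Kalrn, a guanine nucleotide exchange factor gene, was 3.4-fold higher and lost its call without 8 weeks 1 or 8 weeks 3 (highest 0.0554). Gabra2, a gene of a GABA receptor subunit, fell by 2.16 on the log2 scale, and Unc5a, a netrin receptor gene, rose by 1.54. Without 1 week 1, 8 weeks 1 or 8 weeks 3 neither passed (highest 0.0672 and 0.0746), and without 1 week 1 the log2 fold change of Gabra2 was -1.54. Gpnmb and Col12a1 were higher by 1.65 and 1.48 and were not called without 1 week 1, 1 week 2, 8 weeks 1, 8 weeks 3 or 8 weeks 4 (highest 0.0897 and 0.0825), and Col12a1 also not after the length correction (0.0558).

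Ccdc107, Tmem38b, Snhg4 and Bc1 completed the genes with the largest decreases, at log2 fold changes of -2.55, -2.01, -1.88 and -2.14. Without 1 week 1 and 1 week 4, the libraries with the largest share of small structural RNA, these were -1.33, -0.68, -0.69 and -1.14, and none was called (adjusted p = 0.0886, 0.119, 0.0923 and 0.0704). Leaving out the libraries with the most small RNA would shrink the changes of such genes in any case. That fit called 60 genes in all, against 952 with all libraries, so a lost call says little. After the length correction the log2 fold change of Bc1 was -1.09. Ccdc107, Tmem38b and Snhg4 overlap annotated small RNAs, and Bc1 is itself a small structural RNA. The share of counts on small structural RNA was 4.72 ± 3.58% (SD, n = 4) at 1 week and 1.58 ± 0.36% at 8 weeks, and ran from 1.01% to 9.14% within the 1 week libraries. This share covers the rows of miscellaneous RNA, Rmrp, Rpph1 and also the protein-coding gene Ccnb1ip1. Ccnb1ip1 was the larger part of it, with 3.04 ± 2.70% of the counts at 1 week and 0.92 ± 0.19% at 8 weeks. The difference in the share did not pass an exact permutation test (two-sided, p = 0.1429). Ccdc107 lost its call without 8 weeks 3 (0.0533), and Tmem38b and Snhg4 without 1 week 1, 8 weeks 1 or 8 weeks 3 (highest 0.075 and 0.069).

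**Figure D2:**
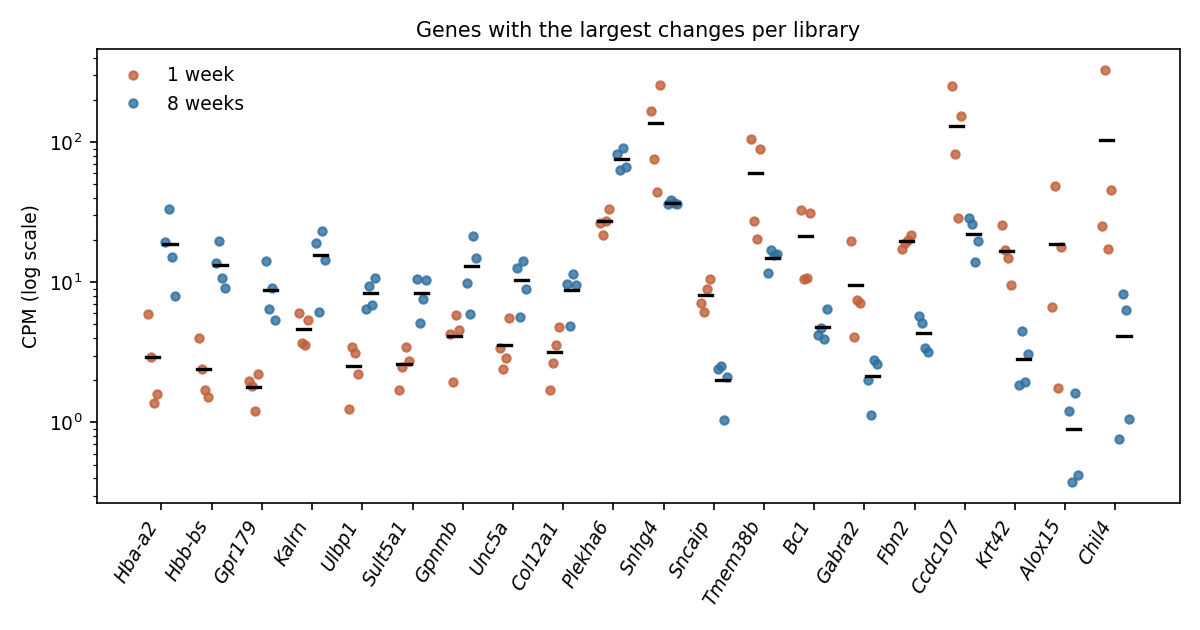
CPM on a log scale per library for the 10 called genes with the largest and the 10 with the smallest log2 fold change chosen by the naming rule, points by age and bars at the group mean of 4 libraries. The naming rule took only genes whose groups do not overlap, so the lack of overlap is not a result. The 1 week libraries of Chil4 (104 ± 150 CPM) and Alox15 (18.9 ± 21.2 CPM) spread widely.

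Of 21 suprabasal keratin and differentiation genes, 5 fell, 1 rose and 15 were not called. Krt17 (ENSMUSG00000035557, chromosome 11, 100256217 to 100261029) was 661 ± 206 CPM (SD, n = 4) at 1 week and 225 ± 34.7 CPM at 8 weeks, a log2 fold change of -1.56 (SE 0.20, adjusted p = 0.00269). Krt16 was 121 ± 29.2 and 53.4 ± 6.24 CPM, and Krt6b (ENSMUSG00000023041, chromosome 15, 101676023 to 101680287) 26.4 ± 2.91 and 10.2 ± 1.3 CPM, with log2 fold changes of -1.18 (SE 0.16, adjusted p = 0.00367) and -1.38 (SE 0.14, adjusted p = 0.00043). Krt42, a type I keratin gene beside Krt17, fell from 16.8 ± 6.64 to 2.84 ± 1.23 CPM. These 4 keratins were lower in all 4 libraries of 8 weeks than in any of 1 week and kept their calls with each library left out and with the length correction. Reads of the closely related Krt6a and Krt6b and of Krt16, Krt17 and Krt42 can be shared between them. The other members called, chosen for mention after their values were seen, were Krt6a and Krt24, which fell by 0.99 and 0.70 on the log2 scale, and Notch3, a Notch receptor gene, which rose by 0.62. After correction Krt24 and Notch3 had log2 fold changes of -0.57 and 0.31 and were not called (adjusted p = 0.0651 and 0.194).

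The list of suprabasal genes was lower as a group (camera adjusted p = 0.00152, adjusted p = 0.735 with an estimated correlation), with 1 member higher and 7 lower adjusted over the list alone. Its adjusted p was 0.0702 without 1 week 4, 0.0979 with limma-voom and 0.221 by fry. Krt4, Krt13 and Krt1 were positive and not called by edgeR (Krt4 passed in the authors' DESeq2 table, 0.035), so the members did not all go 1 way. Of 16 basal keratinocyte and hemidesmosome genes 1 was called, Dst, which encodes dystonin of the hemidesmosome. It rose by 0.69 (SE 0.12, adjusted p = 0.014) and had a log2 fold change of 0.27 after the length correction (adjusted p = 0.206), its longest transcript being 23279 bp. Krt14 stood at 8417 ± 781 and 6006 ± 1015 CPM (SD, n = 4; adjusted p = 0.0767, 0.0376 without 8 weeks 2, and 0.00724 in the authors' table).

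**Figure D3:**
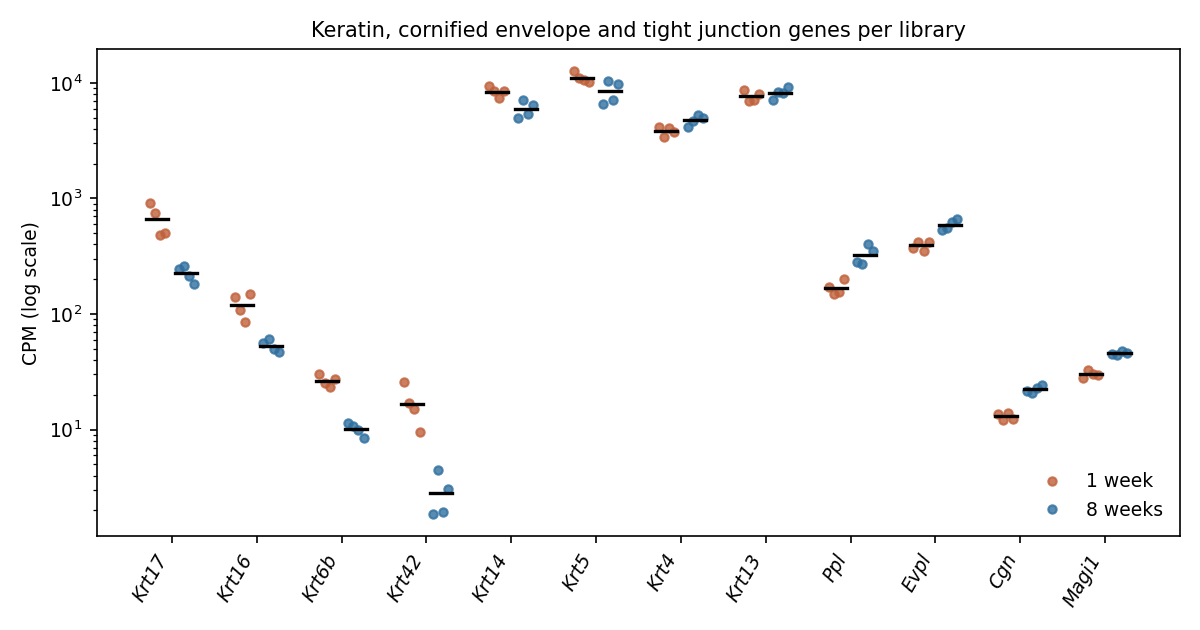
CPM on a log scale per library for keratin, cornified envelope and tight junction genes, points by age and bars at the group mean of 4 libraries. Krt17, Krt16, Krt6b and Krt42 are lower in every 8 weeks library than in any 1 week library, Krt5, Krt14, Krt4 and Krt13 were not called by edgeR, and Ppl, Evpl, Cgn and Magi1 are higher in every 8 weeks library.

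Of 14 tested cornified envelope genes 2 rose and 12 were not called. Ppl (periplakin, a plakin of the envelope; ENSMUSG00000039457, chromosome 16, 5086291 to 5132421) was 169 ± 23.2 CPM (SD, n = 4) at 1 week and 326 ± 63.0 CPM at 8 weeks, a log2 fold change of 0.95 (SE 0.14, adjusted p = 0.00745). Evpl, the gene of its partner envoplakin, was 394 ± 35.3 and 594 ± 61.8 CPM (log2 fold change 0.59, SE 0.11, adjusted p = 0.0165). Evpl was not called without 1 week 1 or 8 weeks 3 (highest adjusted p = 0.0538), nor after the length correction (0.113). Lor and Flg, genes of keratinizing epidermis set in advance, were scarce. Lor stood at 2.27 ± 0.97 and 1.56 ± 0.36 CPM and Flg at 1.47 ± 0.40 and 1.55 ± 0.18 CPM, neither called (adjusted p = 0.371 and 0.897). The list did not pass as a group (camera adjusted p = 0.678).

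Of 17 tight junction genes 3 rose and 14 were not called. Adjusted over the list alone 7 were higher and 2 lower. Cgn, the gene of the junctional adaptor cingulin, was 13.1 ± 0.91 CPM (SD, n = 4) at 1 week and 22.6 ± 1.64 CPM at 8 weeks (log2 fold change 0.79, SE 0.12, adjusted p = 0.00807), and Magi1, a scaffold gene, 30.2 ± 2.07 and 46.0 ± 1.40 CPM (0.60, SE 0.09, adjusted p = 0.00829). Patj, a polarity gene with a log2 fold change of 0.38, was not called after the length correction (0.279), nor without 1 week 1, 1 week 2, 1 week 3, 8 weeks 1, 8 weeks 3 or 8 weeks 4 (highest 0.114). The claudin genes Cldn1 and Cldn4 had log2 fold changes of -0.06 (positive with library size alone) and -0.68 and were not called (adjusted p = 0.89 and 0.126). As a group the list had a camera adjusted p of 0.0588 (0.0474 without 8 weeks 1, 0.0499 with no filter, 0.023 with the stricter filter, and 0.513 with an estimated correlation). Of 21 desmosome and adherens junction genes 1 was called, the catenin gene Ctnnd1, at 0.54, a call lost with any library left out except 8 weeks 2 (highest 0.129) and after correction (0.119). The camera adjusted p of that list was 0.173. By fry, which tests whether a list moves on balance 1 way, both junction lists were higher (adjusted p = 0.0118 and 0.0297), and neither was after correction (0.0525 and 0.887).

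Cers4, a ceramide synthase gene (ENSMUSG00000008206, chromosome 8, 4493026 to 4531680), was the 1 gene called among 19 of the epidermal lipid barrier. It was 23.8 ± 3.14 CPM (SD, n = 4) at 1 week and 44.6 ± 2.64 CPM at 8 weeks, a log2 fold change of 0.91 (SE 0.11, adjusted p = 0.00269). After the length correction Cers3 was called as well, at 0.41 (adjusted p = 0.0459, 0.055 before, and 0.0401 in the authors' table). The list had a camera adjusted p of 0.815, with 13 of its members at a negative fold change and a median of -0.14, while camera gave the direction as higher.

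Of 21 genes of microbial pattern recognition edgeR called 0, adjusted over all genes and over the list alone (camera adjusted p = 0.815). After the length correction 1 was called, Nod2, a gene of an intracellular receptor of bacterial peptidoglycan, at -0.58 (adjusted p = 0.0459), and 2 were higher and 1 lower over the list alone. Tlr4, the lipopolysaccharide receptor, was 3.92 ± 0.61 CPM (SD, n = 4) at 1 week and 6.66 ± 1.06 CPM at 8 weeks (log2 fold change 0.76, SE 0.22, adjusted p = 0.0565, 0.0374 without 8 weeks 2, and 0.0267 in the authors' DESeq2 table), Tlr2 1.95 ± 1.14 and 1.40 ± 0.29 CPM (adjusted p = 0.466), and the adaptor gene Myd88 40.9 ± 9.36 and 37.8 ± 2.34 CPM (adjusted p = 0.625). Of 17 negative regulators of innate signalling edgeR called 0 over all genes (Nfkbia and Socs1 passed in the authors' table, 0.0271 and 0.0354, and Nfkbia by edgeR without 1 week 3 or 8 weeks 2, lowest 0.0333), and 1 higher and 4 lower over the list alone (camera adjusted p = 0.173, 0.0276 without 1 week 3, 0.0416 with the block of the library names, and adjusted p = 0.842 with an estimated correlation). Of 35 interferon-stimulated genes edgeR called 0 on either basis, and 30 had a negative fold change (median -0.49). The camera adjusted p of that list was 0.173, and 0.0015 without 1 week 1, 0.00101 without 1 week 3, 0.000967 without 8 weeks 3, 0.0398 with library size alone and 2.8e-11 with the block of the library names (adjusted p = 0.928 with an estimated correlation). Its mean level, as log2(CPM + 1), was 5.25 in 1 week 4 and 2.94 to 4.03 in the other libraries of 1 week. The block of the library names left out the lowest library of 1 week, 1 week 3 (2.94), and the highest of 8 weeks, 8 weeks 3 (4.32). Of 18 MHC class I genes 1 fell, the immunoproteasome gene Psmb10, at -0.93. It was not called without 1 week 1, 1 week 2, 1 week 4, 8 weeks 1, 8 weeks 3 or 8 weeks 4 (highest 0.115), nor after correction (0.135). That list had a camera adjusted p of 0.808 (0.00921 with the block of the library names, and adjusted p = 0.928 with an estimated correlation).

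Cxcl14, a chemokine gene of epithelia (ENSMUSG00000021508, chromosome 13, 56288643 to 56296551), was 33.9 ± 4.68 CPM (SD, n = 4) at 1 week and 12 ± 3.16 CPM at 8 weeks, a log2 fold change of -1.50 (SE 0.17, adjusted p = 0.00144), and kept its call with each library left out. Among 16 epithelial cytokine and chemokine genes it was the 1 that fell. Il33, an alarmin gene, rose from 0.83 ± 0.55 to 2.76 ± 0.89 CPM (adjusted p = 0.0422), a call that was lost with any library left out except 1 week 1 or 8 weeks 2 (highest 0.106). That list had a camera adjusted p of 0.112 (0.0196 without 1 week 3, 0.049 with library size alone, 0.00158 with the block of the library names, and adjusted p = 0.735 with an estimated correlation). Of 9 antimicrobial genes 1 was called: Ccl28, a mucosal chemokine gene, fell from 1.85 ± 1.01 to 0.40 ± 0.17 CPM (adjusted p = 0.0336), lost without 1 week 1, 1 week 4, 8 weeks 1, 8 weeks 3 or 8 weeks 4 (highest 0.113). The defensin gene Defb1 was 3.39 ± 1.80 and 6.36 ± 0.98 CPM and not called (adjusted p = 0.15). Lcn2 and S100a8 had 44 and 16 counts over the 8 libraries and were not tested. Of 13 genes around IL-17 and IL-22 the receptor gene Il17re rose by 0.50 (adjusted p = 0.0309), lost without 1 week 1, 1 week 3, 1 week 4, 8 weeks 1 or 8 weeks 3 (highest 0.1). These lists had camera adjusted p values of 0.173 and 0.485.

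Of 23 Wnt and Hedgehog genes 3 fell and 1 rose. Axin2, a target and inhibitor of Wnt signalling, was 38.6 ± 4.12 CPM (SD, n = 4) at 1 week and 25.1 ± 1.65 CPM at 8 weeks (log2 fold change -0.62, SE 0.11, adjusted p = 0.0128), and Wnt5a, a Wnt ligand gene, 39.9 ± 5.61 and 25.1 ± 2.64 CPM (-0.67, SE 0.12, adjusted p = 0.0153). Lgr6, a receptor gene known as a marker of epithelial stem cells, was 40.3 ± 4.01 and 22.7 ± 5.98 CPM (-0.83, SE 0.17, adjusted p = 0.0193). These 3 kept their calls after the length correction (adjusted p = 0.00954, 0.00681 and 0.0215). Axin2 and Wnt5a were not called without 8 weeks 3 (0.052 and 0.0533), nor Lgr6 without 1 week 1, 8 weeks 1 or 8 weeks 3 (highest 0.0653). The transcription factor gene Tcf7l2 rose by 0.50, a call that did not hold without 1 week 1, 1 week 2, 1 week 4, 8 weeks 1, 8 weeks 3 or 8 weeks 4 (highest 0.122) or after correction (0.0605). After correction 0 members were higher and 4 lower. The members went both ways before it and the list had a camera adjusted p of 0.823.

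Of 38 cell cycle genes 1 was called over all genes and 0 over the list alone. This was Cenpe, a kinetochore motor gene, at 0.47 (adjusted p = 0.0389), and its call was lost without 1 week 1, 1 week 2, 1 week 4, 8 weeks 1, 8 weeks 3 or 8 weeks 4 (highest 0.11) and after correction (0.249). The proliferation marker Mki67 was 1162 ± 269 CPM (SD, n = 4) at 1 week and 1301 ± 260 CPM at 8 weeks (log2 fold change 0.16, SE 0.18, adjusted p = 0.582), and the list had a camera adjusted p of 0.278 (0.00156 without 1 week 3, 4.74e-05 with the block of the library names, and adjusted p = 0.928 with an estimated correlation). Of 13 imprinted and fetal growth genes 4 rose and 2 fell. The imprinted gene Peg3 was 84.7 ± 22.1 and 158 ± 29.9 CPM (0.90, SE 0.18, adjusted p = 0.0184, lost without 8 weeks 1 or 8 weeks 3, highest 0.0608). The imprinted RNA gene H19 was 288 ± 84.0 and 503 ± 154 CPM (adjusted p = 0.0492), and the cell cycle inhibitor gene Cdkn1c 5.53 ± 1.13 and 2.67 ± 0.78 CPM (adjusted p = 0.0455). H19 kept its call only without 1 week 3 or 8 weeks 2 and Cdkn1c only without 8 weeks 2 among the libraries left out (highest 0.146 and 0.133), and neither passed after correction (0.0577 and 0.0903). The other members called, described after their values were seen, were Igf2r and E2f8, higher by 0.39 and 0.55 and not called after correction (0.11 and 0.54, adjusted p = 0.416 and 0.0682), and Dcn, which is also in the list of fibroblast genes. Igf2 had 58 counts over the 8 libraries and was not tested. The list had a camera adjusted p of 0.556.

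Zbtb16, a zinc finger transcription factor gene known to respond to glucocorticoids (ENSMUSG00000066687, chromosome 9, 48654297 to 48836222), was 0.52 ± 0.38 CPM (SD, n = 4) at 1 week and 4.55 ± 1.64 CPM at 8 weeks, an 8.8-fold increase (log2 fold change 3.14, SE 0.49, adjusted p = 0.00891). It was the 1 gene called of 13 in the glucocorticoid list (camera adjusted p = 0.733, median -0.19 and mean 0.10). Of 19 circadian clock genes Npas2, a paralog of Clock, rose by 0.66 (adjusted p = 0.0165, lost without 1 week 1 or 8 weeks 3, highest 0.0556), and the repressor gene Cry1 fell by 0.67 (adjusted p = 0.0296, lost without 1 week 1, 1 week 3, 8 weeks 1, 8 weeks 3 or 8 weeks 4, highest 0.096). The list had a camera adjusted p of 0.808, and the labels give no time of day.

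Of 32 genes of xenobiotic and oxidant metabolism 2 rose and 3 fell (3 and 1 after the length correction, camera adjusted p = 0.815). Cyp2f2, a cytochrome P450 gene, was 96.2 ± 36.9 CPM (SD, n = 4) at 1 week and 256 ± 46.5 CPM at 8 weeks (log2 fold change 1.41, SE 0.26, adjusted p = 0.0145), and kept its call with each library left out. Gpx2, a glutathione peroxidase gene, was 151 ± 17.7 and 88.4 ± 25.6 CPM (-0.77, SE 0.17, adjusted p = 0.0247), and was not called without 1 week 1, 8 weeks 1, 8 weeks 3 or 8 weeks 4 (highest 0.0808). Gclc rose by 0.40, and Aldh1a1 and Cbr3 fell by 1.65 and 0.51. Gclc lost its call with any library left out except 1 week 3 or 8 weeks 2, Aldh1a1 with any except 1 week 2, and Cbr3 with any except 8 weeks 2 (highest 0.107, 0.134 and 0.129). Aldh1a1 and Cbr3 did not pass after correction either (0.0788 and 0.101). Of 32 cholesterol and fatty acid synthesis genes 1 fell, the isomerase gene Idi1, at -0.54 (adjusted p = 0.0258, lost without 1 week 1, 8 weeks 1, 8 weeks 3 or 8 weeks 4, highest 0.0839), and 7 were lower adjusted over the list alone. That list had a camera adjusted p of 0.0525, which passed without 1 week 3, 8 weeks 1 or 8 weeks 4 (0.000249, 0.0223 and 0.0372), with no filter (0.0436), with limma-voom (0.0156), with the block of the title numbers (0.0269), with the block of the library names (0.00312) and after the length correction (0.000642, and 0.739 with an estimated correlation).

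Of 52 cytosolic ribosomal protein genes 8 fell and 44 were not called, and all 52 had a negative log2 fold change (median -0.42), as with each of the 3 other scalings, which called 2 to 12 of them. Adjusted over the list alone 48 were lower. Rps24 was 2573 ± 371 CPM (SD, n = 4) at 1 week and 1736 ± 269 CPM at 8 weeks, Rps3 2274 ± 256 and 1522 ± 293 CPM, and Rpl27 226 ± 46.4 and 151 ± 24.8 CPM, with log2 fold changes of -0.57, -0.58 and -0.58. Each of the 3 lost its call in 6 or more of the fits with 1 library left out, 1 week 1, 1 week 4, 8 weeks 1, 8 weeks 3 and 8 weeks 4 among the libraries (highest 0.128, 0.131 and 0.129). These transcripts were short, with a median longest transcript of 1140 bp. After the length correction the median was -0.19 and 48 of the 52 were negative, with 1 gene lower over all genes and 4 over the list alone. Rps3 and Rpl27 were then not called (0.0528 and 0.218). Camera gave an adjusted p of 6.79e-19 before and 2.73e-07 after correction (adjusted p = 0.648 and 0.739 with an estimated correlation), and fry 0.163 before. Of 12 mitochondrially encoded transcripts edgeR called 0 on either basis, 10 had a positive fold change (median 0.35) and the camera adjusted p was 0.0588. Without 1 week 3, 8 weeks 2, 8 weeks 3 or 8 weeks 4 it was 0.000694, 0.0347, 0.0467 and 0.0498, with no filter 0.0272, with the stricter filter 0.0259, with limma-voom 0.0183, with the block of the title numbers 0.026, with the block of the library names 0.000196, and after the length correction 8.31e-06, with 7 members higher over the list alone (adjusted p = 0.739 with an estimated correlation).

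Of 26 genes of dissociation and immediate early stress 2 fell, the heat shock genes Hspb1 and Hsph1, at -0.52 and -0.47 (adjusted p = 0.0336 and 0.0341). After the length correction Hspb1 had a log2 fold change of -0.26 and was not called (0.115). Hspb1 was not called without 1 week 1, 1 week 4, 8 weeks 1, 8 weeks 3 or 8 weeks 4, nor Hsph1 without 1 week 1, 1 week 2, 8 weeks 3 or 8 weeks 4 (highest 0.107 and 0.111). Adjusted over the list alone 3 were lower. The list was lower by camera (adjusted p = 0.0423, and 0.842 with an estimated correlation). Its adjusted p was 0.0682 without 8 weeks 3, 0.116 with limma-voom, 0.051 with the block of the title numbers, 0.0576 with protein-coding genes alone and 0.509 by fry, and without 1 week 4 its direction turned (0.795).

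Among markers of other cells, 2 of 10 tested fibroblast and matrix genes fell, the decorin gene Dcn (990 ± 113 CPM at 1 week and 541 ± 169 CPM at 8 weeks, SD, n = 4) and the collagen gene Col6a1 (5.83 ± 1.24 and 2.37 ± 0.98 CPM), with log2 fold changes of -0.87 and -1.30. Dcn was not called without 1 week 1, 8 weeks 1 or 8 weeks 3, nor Col6a1 without 1 week 1, 1 week 3, 8 weeks 1 or 8 weeks 3 (highest 0.0742 and 0.111). Among members below the filter, Col1a1, Col1a2, Col3a1 and Pdgfra had 50, 39, 30 and 23 counts over the 8 libraries. With these so scarce, the fall of Dcn cannot be read as a loss of fibroblasts. The list had a camera adjusted p of 0.0798 (0.0372 without 8 weeks 4, 0.0398 with library size alone, and 0.0253 after the length correction). With an estimated correlation it was adjusted p = 0.513, and adjusted p = 0.381 after the length correction. Of 3 tested Langerhans, dendritic cell and macrophage genes the chemokine receptor gene Cx3cr1 fell from 8.85 ± 5.42 to 2.58 ± 0.69 CPM, and of 4 MHC class II genes H2-Ab1 fell from 19.1 ± 4.38 to 8.77 ± 2.56 CPM. Cx3cr1 lost its call without 1 week 1, 1 week 3, 8 weeks 1, 8 weeks 3 or 8 weeks 4 (highest 0.101) and with limma-voom (0.0672), and H2-Ab1 without 1 week 1, 8 weeks 1 or 8 weeks 3 (highest 0.063) and after correction (0.0712). The list of melanocyte, Schwann cell and adipocyte genes (6 tested) had a camera adjusted p of 0.644. The lists of T and NK cells (2 tested), neutrophils and mast cells (2), endothelium and mural cells (7), skeletal muscle (5) and salivary gland (3) had 0 genes called by edgeR, on either basis. Camera adjusted p values were 0.96 for endothelium and 0.823 for muscle, and lists with under 5 tested genes were not tested by camera or fry. The leukocyte gene Ptprc had 30 counts over the 8 libraries.

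Of 6 tested erythrocyte and platelet genes 3 rose, and adjusted over the list alone all 6 were higher (camera adjusted p = 1.12e-07, and adjusted p = 0.467 with an estimated correlation). The haemoglobin gene Hbb-bs (ENSMUSG00000052305, chromosome 7, 103826534 to 103828096) was 2.41 ± 1.14 CPM (SD, n = 4) at 1 week and 13.4 ± 4.68 CPM at 8 weeks (log2 fold change 2.47, SE 0.32, adjusted p = 0.00352). Hba-a2 was 2.95 ± 2.08 and 18.9 ± 10.7 CPM (2.68, SE 0.46, adjusted p = 0.0125) and Hba-a1 0.80 ± 0.48 and 5.34 ± 3.45 CPM (2.73, SE 0.50, adjusted p = 0.0153). The 3 genes kept their calls with each library left out and with the length correction, and reads can be shared between Hba-a1 and Hba-a2. A further haemoglobin gene, Hbb-bt, chosen for mention after its value was seen, had a log2 fold change of 1.91 (SE 0.64). It was not called (adjusted p = 0.0798).

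Of the 28 lists it tested, camera with the preset correlation called 1 higher (erythrocytes and platelets) and 3 lower (suprabasal keratins, ribosomal proteins, stress). With an estimated correlation camera called 0 lists, 2 had an unadjusted p under 0.05, and fry called 3. When the 8 libraries were regrouped in all 35 ways into 4 and 4, 32 of the groupings, the real one included, gave at least 4 called lists, so that these list calls did not exceed those of arbitrary groupings. The exact permutation test on the mean level of a list gave p = 0.0286, the smallest possible, for suprabasal keratins, tight junction, desmosome, fibroblasts and erythrocytes, with adjusted p = 0.189 over all lists.

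The number of calls depended on single libraries. It was 71 higher and 59 lower without 1 week 1, 253 and 362 without 1 week 2, 70 and 66 without 8 weeks 1, 843 and 1048 without 8 weeks 2, 48 and 43 without 8 weeks 3, and 203 and 173 without 8 weeks 4. Of the 64 named genes that were called, 22 were called again with each library left out. Without 1 week 1, 8 weeks 1 and 8 weeks 3 together, the libraries with the steepest trends on transcript length, edgeR called 0 genes (1326 at an unadjusted p under 0.05, with no other tool run on these 5 libraries), while 13 lists passed by camera with the preset correlation. The deposited table of the authors, from DESeq2, had 774 genes higher and 763 lower at an adjusted p under 0.05, among them 946 of the 952 edgeR calls in the same direction.

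**Figure D4:**
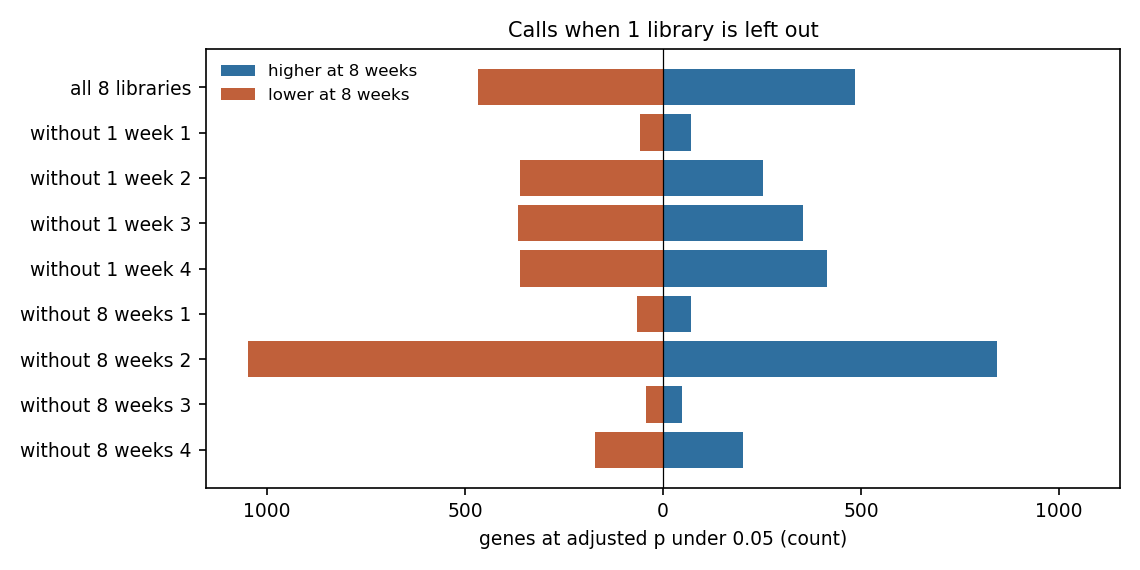
Number of genes called higher (right) and lower (left) at 8 weeks with all 8 libraries and with each library left out in turn. The counts fall to 48 higher and 43 lower without 8 weeks 3 and rise to 843 and 1048 without 8 weeks 2.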

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

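All tests of explanations in this part were chosen after the patterns were seen. The rule for values far from the others of their group, set in advance, marked 19 of 338 groups of 4 libraries, where chance alone marks about 16.9. The marked libraries were spread over 7 of the 8 libraries, with at most 4 in any 1. For each, the gap to the nearest other library was divided by the range of the group. Levels are log2 CPM with a prior count of 2 for genes and mean log2(CPM + 1) for lists.

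At 1 week, 1 week 1 stood apart in Dcn (10.18 against 9.85 to 9.88 in the others, ratio 0.909), Gpx2 (7.47 against 7.15 to 7.16, 0.961) and Eef1a1 (13.35 against 12.94 to 12.96, 0.945). The library 1 week 2 stood apart in Wnt5a (5.60 against 5.18 to 5.25, 0.84), Cyp2f2 (5.37 against 6.76 to 6.89, 0.913), Aldh1a1 (-0.04 against 1.01 to 1.08, 0.938) and Defb1 (-0.15 against 1.97 to 2.23, 0.889). In 1 week 4 the mean levels of the lists for IL-17 and IL-22 (4.06 against 3.73 to 3.74, 0.952) and for Wnt and Hedgehog signalling (5.13 against 5.04 to 5.06, 0.851) were high.

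At 8 weeks, 8 weeks 1 was low in Itgam (-0.78 against 0.06 to 0.18, ratio 0.882) and in the list of suprabasal keratins (6.45 against 6.71 to 6.76, 0.846). The library 8 weeks 2 was low in Patj (6.87 against 6.99 to 7.01, 0.881), Bhlha15 (-0.16 against 0.17 to 0.24, 0.834) and Cd3d (-1.43 against 0.08 to 0.16, 0.952) and high in the list of negative regulators of innate signalling (4.52 against 4.37 to 4.39, 0.87). In 8 weeks 3, Foxm1 was low (5.86 against 6.07 to 6.08, 0.969) and Ifi27l2a high (6.69 against 5.79 to 5.94, 0.84). In 8 weeks 4, H2-Ab1 was low (2.36 against 3.27 to 3.41, 0.868) and Cebpd high (3.40 against 2.70 to 2.77, 0.899).

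A pattern weighed for its explanation was the trend of the fold changes on transcript length. Chance is argued against for the counts of called genes: of the 35 splits of the 8 libraries into 4 and 4, only the real one (1) gave a count as large, 952 genes against at most 1 in any other, and after the length and GC correction again only the real one (1), 385 against at most 1. Against a smooth trend on transcript length and GC content as the whole cause stand the 336 calls kept in the same direction after correction. Other library effects that run with age were not excluded by the correction or by the splits. Corrected calls fell to 27 higher and 40 lower without 1 week 1. They fell to 38 and 49 without 8 weeks 1, and to 25 and 33 without 8 weeks 3. For the 616 calls lost on correction, the median absolute log2 fold change went from 0.55 to 0.34, which partly follows from their choice by the loss. Their median SE went from 0.135 to 0.109, and that of the 336 kept calls from 0.173 to 0.161. A choice by the loss would not by itself lower the SE. Because the length slopes separate the ages, a library effect such as RNA quality and a difference that comes with age cannot be told apart for the lost calls. More unspliced or nuclear RNA at 8 weeks also cannot be told apart: 96.6% of the difference in slope was left with intron length in the model, which goes against it, but the nuclear RNAs Malat1 and Xist were highest in 8 weeks 1 and 8 weeks 3 (Malat1 0.991% and 0.943% of counts, Xist 0.271% and 0.223%), the libraries with the steepest positive slopes, and lowest in 1 week 1 (0.29% and 0.0593%), the steepest negative one. These 2 RNAs were added to the test after their levels had been seen, and neither difference between the ages passed (exact permutation, p = 0.0571 and 0.2). Both are long RNAs, so a trend on transcript length alone could order the libraries in the same way. Their levels therefore cannot decide between that trend and nuclear RNA.

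The decrease of small structural RNAs and of the genes that hold them was also weighed. Reads of small RNAs counted in their host genes are a candidate source: genes that overlap an annotated small RNA were more frequent among the lower calls (35 of 468) than among other tested genes (odds ratio 2.53, Fisher's exact p = 3.98e-06), while among the higher calls the odds ratio was 1.3 (Fisher's exact p = 0.241). Overlap was counted on either strand, and transcript length was not taken into account although short transcripts were frequent among the lower calls. Ccdc107, Tmem38b and Snhg4, seen before, were left in. Whether the amount of small RNA varied through carry-over in the extraction or with age cannot be told apart. Its share, with Ccnb1ip1 counted in, spanned 8.13 percentage points within the 1 week libraries, and 1 week 3, at 1.01%, lay below all 4 libraries of 8 weeks (1.12% to 2.01%). The group difference of -3.15 points did not pass (exact permutation, p = 0.1429). Ccnb1ip1 alone took 6.75% of the counts in 1 week 4 and 0.58% in 1 week 3.

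The third pattern weighed was the rise of haemoglobin transcripts. Blood cells in the sort may be their source, although a sort for epithelial cells would remove intact ones. In a list fixed before the data were examined, 2 tested erythrocyte and platelet genes other than the globins, Alas2 and Itga2b, were higher by more than 2 SE (log2 fold change 2.42, SE 0.87, adjusted p = 0.0961, and 0.38, SE 0.17, adjusted p = 0.158), and neither passed the threshold. Itga2b already had 684 counts over the 1 week libraries, against 115 for Hbb-bs, so it is weak evidence, and Alas2 had 13 counts at 1 week and 92 at 8 weeks. The most abundant transcript, Hba-a2, reached 446 counts in a library. A difference in the epithelial cells that comes with age stays open and was not tested.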

How the results depend on the processing

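The length and GC correction, protein-coding genes alone and the fits without 2 or 3 libraries were chosen after the data had been seen. No called gene was called in the opposite direction in an alternative run, and the signs of those not called again were not compared for all genes. The counts of 484 higher and 468 lower stayed within 1.5 times with the size factors of DESeq2, upper-quartile scaling, the stricter filter and protein-coding genes alone. Without the filter 327 were higher and 265 lower. With library size alone 588 were higher and 255 lower, 69.8% of the calls higher against 50.8% with TMM, and the median of all genes moved by 0.096. The Wald test of DESeq2 gave 1006 higher and 1028 lower, limma-voom 772 and 868, the 2-fold minimum 77 and 173, the block by title numbers 78 and 83, the block by library names 26 and 66 and the length and GC correction 155 and 230. The block by library names held 6 libraries, so blocking and the loss of 1 week 3 and 8 weeks 3 cannot be told apart. With 1 library left out the counts ran from 48 to 843 higher and from 43 to 1048 lower, and with the correction from 25 to 236 and from 33 to 355. Without 1 week 1 and 1 week 4, 31 were higher and 29 lower, and without 1 week 1, 8 weeks 1 and 8 weeks 3 edgeR called 0 and 0 (1326 genes at an unadjusted p under 0.05). Over all 24 sets of 5 libraries that leave out 1 of 1 week and 2 of 8 weeks the total ran from 0 to 2841 (median 39), and over the 6 sets without 2 of the 1 week libraries from 19 to 581. The cause of these differences was not tested, except that fewer libraries give fewer degrees of freedom.

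Of the lists, 1 was higher and 3 lower. Higher were 3 without the filter, 2 with the stricter filter, 2 with limma-voom, 2 with the block by title numbers, 3 with the block by library names, 2 with the correction, 6 without the 3 libraries, 0 with an estimated correlation, 3 by fry, and 1 to 3 with 1 library left out. Lower were 6 with library size alone, 8 with the block by library names, 5 with the correction, 1 without the 2 libraries, 7 without the 3 libraries, 0 with an estimated correlation, 0 by fry, and 1 to 7 with 1 library left out. The list dissociation and immediate early stress turned its direction without 1 week 4 (adjusted p = 0.795, the range with 1 library left out being 0.000437 to 0.795) and without 1 week 1 and 1 week 4 (adjusted p = 0.153). The cause was not tested. Of the 64 named genes called, 48 were called again with the correction and 22 with each library left out. In simulated counts of this depth and number of replicates, 25.4% of genes changed 1.5-fold were recovered.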

Other observations

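All tests in this part except the count of lists over the splits were chosen after the values were seen. A list of target genes of hypoxia-inducible factors was drawn up after the values were seen. Pgam1, Ddit4 and Fam162a had been seen to fall, and of 28 further members (29 tested, as Aldoa has 2 identifiers) 9 fell and 0 rose: Ak4, Ankrd37, Bnip3, Higd1a, Ldha, Ndrg1, Pfkfb3, Pgk1 and Slc2a1. The glucose transporter gene Slc2a1 fell by 0.55 on the log2 scale (SE 0.11, adjusted p = 0.0169), the mitophagy gene Bnip3 by 0.92 (SE 0.18, adjusted p = 0.0169) and the lactate dehydrogenase gene Ldha by 0.52 (SE 0.14, adjusted p = 0.0422). After the length correction Ankrd37 and Ldha did not pass (0.104 and 0.0813). Adjusted over the list alone 14 were lower.

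A hypothesis is that targets of hypoxia-inducible factors may be lower together at 8 weeks. By fry the further members were lower before and after the length correction (p = 0.0105 and 0.0107, adjusted over the 3 lists tried in this way 0.0158 and 0.016), and the exact permutation test on their mean level gave p = 0.0286, the smallest possible. The medians were -0.26 and -0.21. Camera with an estimated correlation, which compares a list with other genes, gave p = 0.0858 beside that exact test. Oxygen, glucose and the handling of the tissue were not measured, so age and handling stay open.

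A further hypothesis, from Chil4 and Alox15, is that targets of IL-4 and IL-13 may be lower together. Of 10 further members 3 fell (Alox12e, Il13ra2 and Ptgs1) and 1 rose (Bcl6), of which Il13ra2 and Ptgs1 did not pass after the length correction (0.0784 and 0.0577). By fry they were lower, with p = 0.00302 after the length correction (adjusted p = 0.00906), a median of -0.41, and p = 0.105 by camera with an estimated correlation (exact permutation, p = 0.0286). From Fbn2 and Col4a1, lower basement membrane and microfibril genes were tried in the same way and not borne out. Fry gave p = 0.102 after correction (exact permutation, p = 0.7429). Before correction, of 20 further members 4 rose (Efemp1, Frem2, Lamb2 and Tgfbi) and 1 fell (Egfl6). After it Frem2 and Lamb2 did not pass (0.27 and 0.135), and Efemp1 and Tgfbi stayed higher. Egfl6 stayed lower, and Lamb1 and Col18a1 were then called lower as well (0.0462 and 0.0236), so the members went both ways.

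From Krt17, Krt6b, Krt16 and Krt42, it was asked whether keratin genes as a family may be lower. Of 29 tested keratin genes 9 fell and 0 rose (8 and 0 with library size alone, 6 and 0 after the length correction). Among the 21 that the naming rule does not include, 5 fell (Krt87, Krt35, Krt6a, Krt18 and Krt24), more often than other tested genes (odds ratio 9.56, Fisher's exact p = 0.000434). Krt6a and Krt24 are members of the fixed list and had been seen, genes are not independent replicates, and reads can be shared between related keratins. Of the 5, Krt87 and Krt6a passed after the length correction (0.0238 and 0.00954), and Krt35, Krt18 and Krt24 did not (0.0519, 0.107 and 0.0651).

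The count of called lists was compared over the splits of the 8 libraries. At least 4 called lists came from 32 of the 35 splits, the real one included, and 15 from the highest, so that chance is not excluded for the 4 lists called with the preset correlation. With an estimated correlation 0 lists were called.

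Among interferon-induced genes, Ifi27l2a was 139 ± 139 CPM (SD, n = 4) at 1 week and 69.5 ± 22.7 CPM at 8 weeks and Iigp1 12.4 ± 16.2 and 2.17 ± 2.18 CPM, neither called. Both were highest in 1 week 4 (346 and 36.1 CPM), and without it the log2 fold changes were -0.03 for Ifi27l2a and -1.04 for Iigp1. The long noncoding RNA Malat1 took 0.403 ± 0.084% of the counts at 1 week and 0.760 ± 0.247% at 8 weeks (exact permutation, p = 0.0571).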
